A study of Escherichia coli K-12 with 22 samples.

How the data were processed

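Total RNA from Escherichia coli K12 strain MG1655 was sequenced with strand-specific small RNA library kits after depletion of ribosomal RNA (rRNA), per the labels' protocols. The protocols name an earlier and a later kit and sequencing platform without saying which library used which, so no batch could be set against the conditions. For each time point, cells from 3 parallel cultures were pooled before RNA was prepared, per the labels' protocols. Each library is therefore 1 pool, and the spread that the tests use is the variation between time points of a condition, not between separate cultures.

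The deposited tables give, for each listed gene, raw read counts on the sense and on the antisense strand, per the file headers. Bowtie is named in the submitters' processing notes; its version, the genome build and the counting tool are not given in the sources used here. The deposited tables also hold TPM values (counts over gene length, scaled within a library), per the file headers. In the values these are proportional to count over gene length, except that TPM is 0 for some genes with reads, each covered over 0.25 of its length or less. The coverage column, per the file headers, is the fraction of a gene's length that reads cover. Deposited TPM and coverage were used only to check the counts. A further column holds peptide counts per gene, per the file headers, from protein samples named in the labels' protocols; its method is not given in the sources used here. The authors' deposited call column was not used.

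The 22 tables list 2330 genes, which is part of the genome. The 6 entries without a gene name held 0.00241% to 0.0544% of the sense reads of a library and were left out. The gene sulA was left out because its antisense count is missing and its TPM is not proportional to its count in the HS and MOPS tables. Of the 2323 genes used, 2253 matched a symbol of the reference table for assembly ASM584v2, which served for gene types only. Positions are those of the deposited tables, and their build is not given in the sources used here. The tables for M-C at 1 h and at 2 h came in pairs with identical values, and each pair was counted as 1 library, which left 20 libraries. Sense reads per library ranged from 954089 to 6897149. The RNA of ssrA, a small stable RNA that rescues stalled ribosomes, took 22.3% to 90.9% of them. A count of 3 reads, the floor for a gene with no read, corresponds to 0.435 to 3.14 CPM (reads scaled to library size alone), depending on the library. Intervals and floors cover counting error only, since PCR copies were not marked.

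Sense counts were tested with edgeR 4.0.16 (quasi-likelihood test with robust dispersion, trimmed mean of M values (TMM) scaling, low-count filter of the package) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05. M-C, M-P and HS (1, 2 and 4 h) were compared with MOPS in 1 fit over 15 libraries with time as a block. MOPS was compared with exponential LB (OD600 0.5 and 1.0) in a fit by condition over these libraries and those of M-C, M-P and HS. Time trends were slopes on log2 hours per condition, fitted over 17 libraries. LB at OD600 3.0 has 1 library, so it was compared by ratio alone, counting genes past 4-fold against both exponential libraries. Antisense counts were tested in the same way with the library sizes and TMM factors of the sense counts. The antisense to sense ratio was tested as the interaction of strand and condition with a term per library and a strand by time term, over genes with a mean of 3 or more antisense and 10 or more sense reads. The antisense share is the percentage of gene-assigned reads on the antisense strand, rRNA and tRNA genes left out, compared by an exact two-sided permutation test. Values quoted as CPM are TMM-scaled, apart from the floors of 3 reads above. TMM-scaled CPM are also divided by the library's TMM factor, which was 0.144 at M-C 4 h and 0.163 at M-C 6 h. On that scale the floors of M-C 4 h and 6 h lie far above their 2.72 and 3.14 CPM by library size alone.

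Lists of genes, 24 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison; the p with an estimated correlation is given where the call is lost. The rule for named genes took, per comparison, the 8 genes higher and the 8 lower with the largest change among those that passed, had a mean CPM of 20 or more and, where times are matched, moved the same way at each, with rRNA and tRNA genes left out. It added fixed sentinel genes, the 3 members of a list with the largest change (or the pair with the highest mean where none passed), and the 4 steepest genes each way per trend. For antisense it took the 5 largest changes each way with a mean of 20 or more antisense reads, and for LB at OD600 3.0 the 10 largest each way with 50 or more reads in the higher library. Sentinels of the rule that are not listed in the tables were not analysed here. Genes with a group at 0 reads are given a lower bound against 3 reads over that group's libraries, and genes with 1 to 3 reads a ratio with its exact 95% counting interval. The tests, lists, naming rule and the first set of alternatives were fixed before the data were examined.

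Overlaps between responses share the MOPS libraries, so unchanged groups were simulated against them 20 times. Alternatives covered other scalings, low-count filters, DESeq2 1.42.0, fits of 2 conditions alone, a fit without the time block, and each library left out in turn. Python 3.11.15 with SciPy 1.17.1 ran the permutation tests.

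The tests were tested on simulated counts drawn from the libraries' own means and sizes. For M-C against MOPS, over 2136 genes, 1.49% of genes changed 2-fold, 16.4% of those changed 4-fold and 69.7% of those changed 8-fold were recovered. The same shares were 1.49%, 35.8% and 84.8% for M-P, and 1.49%, 25.4% and 77.3% for HS, over 2136 genes each. For MOPS against LB, over 2164 genes, they were 0.00%, 11.9% and 39.4%. For a slope of 1 on the log2 scale per doubling of time, over 2150 genes, 77.6% were recovered in HS, 31.3% in MOPS, 8.96% in M-C and 32.8% in M-P. For antisense counts changed 8-fold, over 799 genes, 45.5% were recovered in M-C, 86.4% in M-P and 71.2% in HS. For the ratio changed 8-fold, over 691 simulated genes, 18.6%, 63.5% and 35.1% were recovered in M-C, M-P and HS. False calls were 0.00% to 10.2% of the calls, and camera called the changed list and 0 of 20 unchanged lists. The simulated genes were drawn independently and the changed list held only genes made to rise. The camera result therefore cannot show how often lists of correlated genes are called falsely. Changes of 2-fold were thus mostly below what these libraries can show.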

Results

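The series asked how transcription on both strands of Escherichia coli K12 MG1655 responds to changes of environment. Cells were grown at 37 °C in LB, a rich medium, and sampled at an optical density (OD600) of 0.5, 1.0 and 3.0. Cells at OD600 1.0 were moved to MOPS, a defined minimal medium with glucose and phosphate. Others were moved to the same medium without glucose (M-C, carbon starvation), without phosphate (M-P, phosphorus starvation), or in full at 48 °C (HS, heat shock). MOPS, M-C and M-P were sampled at 1, 2, 4 and 6 h, and HS at 15 and 30 min and 1, 2 and 4 h. The tables of M-C at 1 h and 2 h were each present as 2 copies with identical values under separate sample labels. Each pair was counted as 1 sample and gives no replicate. The second sample of each pair is labelled paired-end, and no layout is given for any other sample. Which sample of a pair the counts came from cannot be told.

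The 20 libraries held 954089 (M-C 6 h) to 6897149 (M-P 4 h) sense reads and 714 (M-C 6 h) to 37679 (HS 1 h) antisense reads over 2323 genes. The RNA of ssrA, which frees stalled ribosomes, made up 45.4% ± 18.2 of sense reads in MOPS (SD, n = 4), 82.8% ± 9.59 in M-C (n = 4), 55.5% ± 11.6 in M-P (n = 4) and 41.9% ± 9.48 in HS (n = 5). Reads outside ssrA ranged from 87125 (M-C 6 h) to 3390794 (M-P 1 h). Residual rRNA took 1.40% ± 0.0854 of sense reads in M-C, 0.139% ± 0.0792 in M-P and 0.360% ± 0.162 in MOPS (n = 4 each). Transfer RNA took 12.2% ± 4.55 in HS (n = 5), 4.26% ± 1.53 in MOPS, 1.73% ± 0.677 in M-C and 0.346% ± 0.235 in M-P (n = 4 each). The M-P libraries, at 0.165% to 0.692%, and the M-C libraries, at 0.897% to 2.46%, lay below every MOPS library (2.92% to 6.29%).

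Phosphorus starvation was compared with full medium to find the genes that answer the loss of phosphate. All 25 tested members of the Pho regulon, the genes under the phosphate sensor PhoR and its partner PhoB, rose in M-P. The phosphonate uptake and breakdown genes at positions 4316029 to 4323188 changed most. phnD rose by 12.78 ± 1.25 on the log2 scale (SE; edgeR, 4 libraries against 4, adjusted p = 2.15e-05). phnC (ECK120000705) had 45532 reads in M-P and 2 in MOPS, a ratio of 13691 with a 95% counting interval of 3790 to 113054. phnE_1, phnE_2 and phnK had 0 reads in MOPS and were at least 1545-fold, 465-fold and 515-fold higher. phnF, phnH and phnI had 1 to 3 reads in MOPS, with ratios of 2130 (589 to 17592), 1352 (463 to 6560) and 2554 (458 to 100903).

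phoA (ECK120000718, 400971 to 402386, plus strand), which encodes alkaline phosphatase, rose by 7.77 ± 0.78 in M-P (adjusted p = 2.15e-05). It was at 4175, 16294, 18190 and 7834 CPM at 1, 2, 4 and 6 h in M-P, and at 97.9, 67.5, 54.0 and 29.0 CPM in MOPS. ugpB, the glycerol phosphate binding protein gene, rose by 7.28 ± 1.40 (adjusted p = 0.00545) and pstS, the phosphate binding protein gene, by 6.81 ± 1.35 (adjusted p = 0.00664). The list's median change was 7.28, also with genes of few reads at their bounds, and it stood apart from other genes (camera adjusted p = 5.45e-55, and adjusted p = 0.0205 with an estimated correlation). Adjusted over the list alone, 25 of 25 passed as well.

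**Figure D1:**
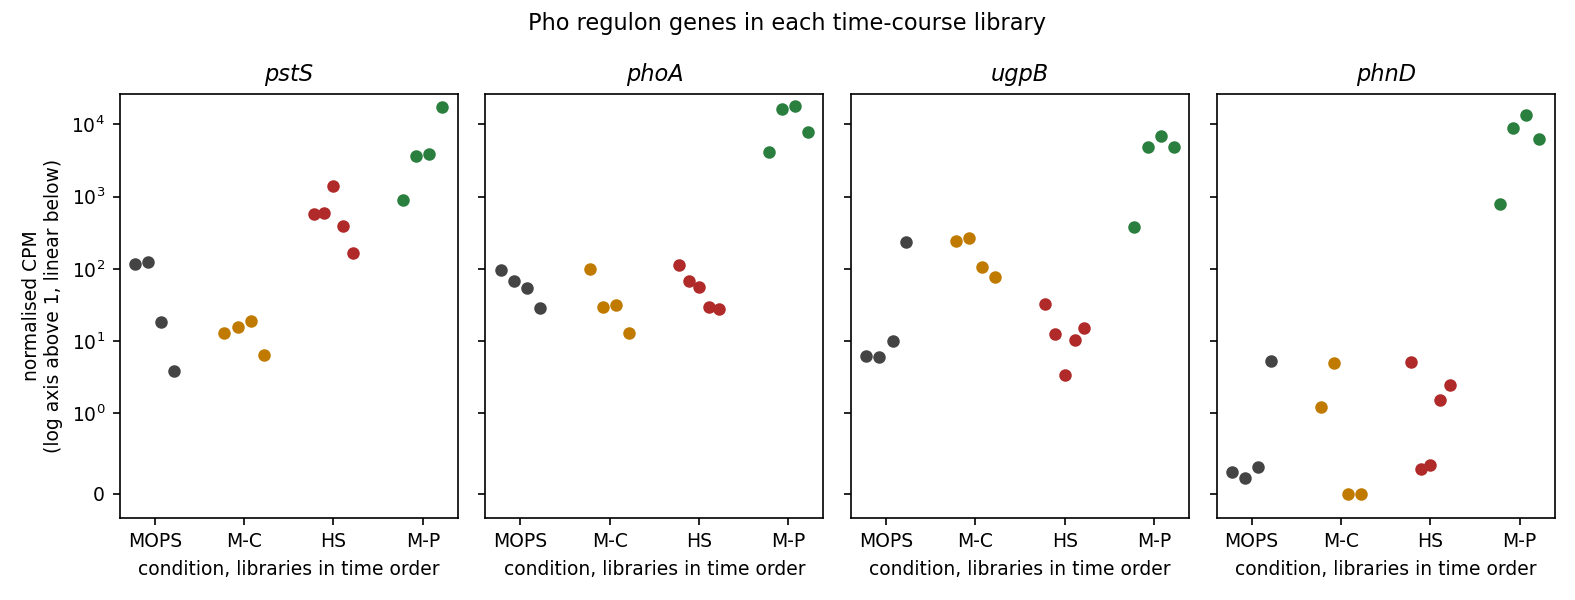
TMM-scaled CPM (log axis above 1) of 4 Pho regulon genes in each MOPS, M-C, HS and M-P library, in order of time. phoA ran from 4175 to 18190 CPM in M-P and from 29.0 to 97.9 CPM in MOPS.

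Of 45 ribosomal protein genes 7 fell in M-P and 38 did not pass, with 21 lower when adjusted over the list alone and 20 without MOPS 6 h (median −1.14; camera adjusted p = 2.26e-18, but adjusted p = 0.490 with an estimated correlation). rplK fell by 2.75 ± 0.51 (adjusted p = 0.00362), rplA by 2.62 ± 0.52 (0.00558) and rpsQ by 2.45 ± 0.61 (0.0258). ssrS, the 6S RNA that binds RNA polymerase, fell by 4.19 ± 0.80 (0.00456), and purE, of purine synthesis, by 4.02 ± 0.83 (0.00788). tdcG, of threonine breakdown, fell by 3.32 ± 0.72 (0.0109), and the arginine transport genes artP and artQ by 2.61 ± 0.49 (0.00406) and 2.38 ± 0.49 (0.00807). Of 16 rRNA genes 5 fell (11 when adjusted over the list alone; median −1.68; camera adjusted p = 6.09e-08, but adjusted p = 0.490 with an estimated correlation). The M-P libraries also held less tRNA than MOPS. For rRNA and ssrS, a response to the loss of phosphate and another preparation of the M-P libraries cannot be told apart. purE alone of 17 nucleotide synthesis genes fell (4 when adjusted over the list alone, 6 without MOPS 6 h; median −1.13; camera adjusted p = 0.000995, but adjusted p = 0.809 with an estimated correlation). cspI rose by 2.93 ± 0.75 (0.0299), lacZ by 2.31 ± 0.64 (0.0432) and umuD by 2.02 ± 0.47 (0.0157), and rimM fell by 1.68 ± 0.46 (0.0432).

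In all, 156 of 2136 genes changed in M-P, 104 higher and 52 lower, against 91 higher and 24 lower with rRNA and tRNA genes left out. The count was 103 without MOPS 1 h, 82 without MOPS 2 h, 99 without MOPS 4 h, 259 without MOPS 6 h, 79 without M-P 2 h and 87 without M-P 4 h. purE did not pass without M-P 2 h (−3.37) or 4 h (−3.55), tdcG without M-P 4 h (−3.14), and rpsQ without MOPS 1, 2 or 4 h or M-P 2 or 4 h (−2.45 to −2.10). Nor did cspI pass without MOPS 1 or 2 h or M-P 1 h (1.81 to 3.17), lacZ without MOPS 1 or 2 h or M-P 2, 4 or 6 h (1.98 to 2.36), umuD without MOPS 2 or 4 h or M-P 4 h (1.86 to 1.99), or rimM without MOPS 2 or 4 h or M-P 2, 4 or 6 h (−1.81 to −1.48).

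Carbon starvation was compared with full medium to find the genes that answer the loss of glucose. Transcripts of the protein synthesis machinery were lower in M-C. All 45 tested ribosomal protein genes fell (45 also when adjusted over the list alone; median −3.31; camera adjusted p = 1.22e-14, but adjusted p = 0.319 with an estimated correlation). rpsJ fell by 4.59 ± 0.90 on the log2 scale (SE; edgeR, 4 libraries against 4, adjusted p = 0.00145), rpsG (ECK120000897, 3471564 to 3472103, minus strand) by 4.57 ± 0.64 (0.000198), rplC by 4.42 ± 0.78 (0.000741) and rplB by 4.41 ± 0.73 (0.000519). Of 14 translation factor genes 12 fell (median −3.51; camera adjusted p = 0.000309, but adjusted p = 0.319 with an estimated correlation), and 12 fell and 1 rose when adjusted over the list alone. prfA, a release factor gene, fell by 5.13 ± 0.62 (0.000118), tsf, an elongation factor gene, by 4.72 ± 0.72 (0.000334) and prfC by 4.70 ± 0.73 (0.000361). M-C libraries also stood apart in rRNA: all 16 tested rRNA genes were higher (16 also when adjusted over the list alone). The median of this list was 4.39, also with the 1 gene without MOPS reads at its bound. Its camera adjusted p was 3.57e-20, but 0.164 with an estimated correlation.

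Genes of nucleotide synthesis, ATP synthase and glycolysis were lower as well, and part of those of amino acid synthesis. Of 17 nucleotide synthesis genes 15 fell (16 when adjusted over the list alone; median −3.39; camera adjusted p = 3.53e-05, but adjusted p = 0.319 with an estimated correlation), and purE fell by 7.11 ± 1.08 (edgeR adjusted p = 0.000334), purC by 5.66 ± 0.90 (0.000417) and pyrI by 5.40 ± 1.09 (0.00183). All 9 ATP synthase genes fell (median −3.44; camera adjusted p = 0.000544, but adjusted p = 0.407 with an estimated correlation), atpH by 4.36 ± 0.61 (0.000198). All 5 glycolysis genes fell (median −2.05; camera adjusted p = 0.0405, but adjusted p = 0.477 with an estimated correlation and 0.09999 with no time block), pfkA by 3.48 ± 0.61 (0.000713). Of 46 amino acid synthesis genes 20 fell and 26 did not pass (median −2.27; camera adjusted p = 0.107), against 29 that fell without MOPS 6 h (camera adjusted p = 0.00188) and 6 that fell and 2 that rose without M-C 4 h and 6 h (0.304), among them metF by 7.26 ± 2.69 (0.0465), argF by 5.89 ± 1.40 (0.00506) and gltB by 5.83 ± 1.12 (0.00134). Others with large falls were ilvG_2 (−6.69 ± 1.71), yrbN (−6.64 ± 0.72) and sbp, the sulfate binding protein gene (−6.59 ± 1.97).

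Genes for the uptake and use of other carbon sources were higher in M-C. Of 38 such genes under the regulator CRP 19 rose and 0 fell, and 22 rose and 1 fell when adjusted over the list alone (median 1.78; camera adjusted p = 1.99e-10, but adjusted p = 0.319 with an estimated correlation). The galactose binding protein gene mglB rose by 6.21 ± 1.84 (edgeR adjusted p = 0.0166), the trehalose uptake gene treB by 6.08 ± 0.79 (0.000165) and the dicarboxylate uptake gene dctA by 5.66 ± 1.18 (0.00207). Of 10 genes for glyoxylate, acetate and fatty acid use 3 rose (5 without MOPS 6 h, 2 of 8 with no time block; median 1.82; camera adjusted p = 0.000794, but adjusted p = 0.319 with an estimated correlation), fadI by 6.66 ± 2.26 (0.0314), fadJ by 5.58 ± 1.80 (0.0255) and fadD by 5.43 ± 1.38 (0.00753). Of 7 genes of the tricarboxylic acid (TCA) cycle 4 rose (6 rose and 1 fell when adjusted over the list alone, 1 rose with no time block; median 1.74; camera adjusted p = 0.00226, but adjusted p = 0.405 with an estimated correlation), sdhB by 2.45 ± 0.72 (0.0148). sgcB rose by 6.78 ± 0.73 (9.18e-05), sgcX by 5.95 ± 0.73 (0.000118), gudP, a glucarate uptake gene, by 5.66 ± 0.90 (0.000425) and spy3 by 5.62 ± 0.74 (0.000165).

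In M-C 0 of 16 genes of the heat shock regulon of sigma 32 rose and 2 fell (2 and 2 without MOPS 6 h; median −0.61; camera adjusted p = 0.999), and of 11 envelope stress genes of sigma E and Cpx 1 rose and 3 fell (2 and 2 without MOPS 6 h, 0 and 4 with no time block; median −0.82; camera adjusted p = 0.999). Of 14 toxin-antitoxin genes 8 rose (10 when adjusted over the list alone; median 1.45; camera adjusted p = 9.35e-05, but adjusted p = 0.319 with an estimated correlation), mqsR by 4.40 ± 0.86 (edgeR adjusted p = 0.00137) and mqsA by 3.98 ± 0.82 (0.00187). Of 13 genes of the general stress regulon of RpoS 3 rose (3 when adjusted over the list alone, 8 without MOPS 6 h, 2 with no time block; median 1.67; camera adjusted p = 0.000343, but adjusted p = 0.407 with an estimated correlation), yeaH by 3.61 ± 0.66 (0.000936). raiA, whose product binds idle ribosomes, rose by 6.39 ± 1.06 (0.000515) and cstA (ECK120000163), a carbon starvation gene, by 4.83 ± 1.14 (0.00445). fis, a growth phase regulator, fell by 3.51 ± 0.93 (0.00914).

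In all, 828 of 2136 genes changed in M-C, 265 higher and 563 lower. The split depended on scaling and on the libraries used: 412 higher and 437 lower with upper-quartile factors (median of all genes 0.42 higher), 381 and 460 with ssrA left out (0.34 higher). It was 346 and 387 without M-C 4 h and 6 h, where 42 ribosomal protein genes fell. Without MOPS 6 h as well, 472 rose and 515 fell. metF did not pass without any 1 of the libraries but MOPS 2 h and 6 h (−8.94 to −3.02), fadI and fadJ without MOPS 1, 2 or 4 h or M-C 1 or 2 h (4.92 to 6.22 and 4.31 to 5.13), mglB without MOPS 1, 2 or 4 h or M-C 2 h (5.08 to 6.17), and sbp without MOPS 1 h (−3.99), MOPS 2 h (−6.29) or M-C 1 h (−6.79).

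Heat shock at 1, 2 and 4 h was compared with full medium, in a fit that also held MOPS 6 h. Genes of the envelope stress response and of toxin-antitoxin pairs were among those higher. degP (ECK120000456, 180884 to 182308, plus strand), a protease and chaperone of the periplasm, rose by 6.02 ± 0.84 on the log2 scale (SE; edgeR, 3 HS libraries with 4 MOPS libraries in 1 fit, adjusted p = 0.000167). It was at 5516, 5666 and 11707 CPM at 1, 2 and 4 h in HS and at 160, 73.3 and 69.2 CPM in MOPS. spy, a periplasmic chaperone gene, rose by 5.57 ± 0.76 (0.000146) and rseB, of the control of sigma E, by 3.91 ± 0.73 (0.000960). Of 11 genes of the sigma E and Cpx list 4 rose (4 when adjusted over the list alone; median 0.85; camera adjusted p = 0.0446, but adjusted p = 0.677 with an estimated correlation, 0.0525 without MOPS 6 h and 0.0790 with no time block). Of 14 toxin-antitoxin genes 9 rose (10 when adjusted over the list alone; median 2.16; camera adjusted p = 0.000189, but adjusted p = 0.566 with an estimated correlation), higB by 6.21 ± 0.57 (1.77e-05), hipB by 2.75 ± 0.56 (0.00193) and mazE by 2.52 ± 0.44 (0.000587).

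Of 16 genes of the heat shock regulon of sigma 32 only 2 rose past the test at 1 to 4 h (2 when adjusted over the list alone, 4 without MOPS 6 h; median 0.05; camera adjusted p = 0.731). ibpB, a small heat shock protein gene, rose by 5.36 ± 1.41 (edgeR adjusted p = 0.00919) and rpoH, the gene of sigma 32 itself, by 3.44 ± 0.87 (0.00704). The chaperone genes groL (−0.88 ± 1.23, edgeR adjusted p = 0.598) and clpB (−0.53 ± 1.10, 0.730) did not pass. The fit includes MOPS 6 h, which has no HS library of its time. There groL was at 10012 CPM (596 to 1485 in the other MOPS libraries) and clpB at 13997 CPM (543 to 1275). These 2 estimates therefore rest in part on that library. Of 12 SOS response genes 4 rose (camera adjusted p = 0.176), ydjM by 4.67 ± 0.53 (4.98e-05). Among genes of less known role ydeT rose by 7.84 ± 0.73 (1.77e-05), ydeS by 6.60 ± 0.81 (8.09e-05), ydeM by 6.50 ± 0.64 (2.35e-05), yadC by 5.89 ± 0.57 (2.35e-05) and ybcK by 5.82 ± 0.78 (0.000138). ybfH had 2888 reads in HS and 3 in MOPS, a ratio of 999 (95% counting interval 341 to 4845). pstS rose by 3.28 ± 1.12 (0.0329).

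Genes of central metabolism and of synthesis were lower in HS. Of 46 amino acid synthesis genes 31 fell (34 when adjusted over the list alone; median −3.26; camera adjusted p = 4.41e-07, but adjusted p = 0.758 with an estimated correlation), cysP by 6.01 ± 1.82 (edgeR adjusted p = 0.0187), leuC by 5.49 ± 1.29 (0.00519) and hisG by 3.79 ± 1.04 (0.0113). All 5 glycolysis genes fell (median −4.01; camera adjusted p = 0.000189, but adjusted p = 0.566 with an estimated correlation), fbaA (ECK120000276) by 5.35 ± 0.68 (0.000101) and pgk by 4.28 ± 0.63 (0.000229). Of 7 TCA cycle genes 5 fell (6 when adjusted over the list alone; median −3.86; camera adjusted p = 0.000189, but adjusted p = 0.566 with an estimated correlation), sucA by 4.87 ± 0.81 (0.000466). Of 9 ATP synthase genes 7 fell (8 when adjusted over the list alone; median −3.21; camera adjusted p = 0.000189, but adjusted p = 0.660 with an estimated correlation), atpG by 4.04 ± 0.64 (0.000332). nuoE, nuoF and nuoG, of respiratory complex I, fell by 5.60 ± 0.90 (0.000362), 5.33 ± 0.86 (0.000362) and 5.36 ± 0.79 (0.000215). The porin gene ompF fell by 5.43 ± 0.71 (0.000123) and the peptide uptake gene dppD by 5.45 ± 0.56 (3.76e-05).

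Of 18 nitrogen limitation genes 6 fell (9 with no time block; median −1.42; camera adjusted p = 0.00311, but adjusted p = 0.677 with an estimated correlation), glnQ by 4.61 ± 0.52 (edgeR adjusted p = 4.98e-05). Of 22 anaerobic and fermentation genes 8 fell (median −1.35; camera adjusted p = 0.00311, but adjusted p = 0.758 with an estimated correlation), pflB by 5.14 ± 0.95 (0.000903), a gene that may share reads with tdcE. Of 17 nucleotide synthesis genes 7 fell and 1 rose (median −1.05; camera adjusted p = 0.0340, but adjusted p = 0.758 with an estimated correlation and 0.105 with no time block), purB by 5.29 ± 0.72 (0.000146). Of 45 ribosomal protein genes 3 rose and 42 did not pass (median 0.08, and −0.13 without MOPS 6 h; camera adjusted p = 0.824). aceA, of the glyoxylate bypass, fell by 5.08 ± 1.10 (0.00279).

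In all, 831 of 2136 genes changed in HS, 460 higher and 371 lower. The split was 624 and 255 with median-ratio factors (median of all genes 0.46 higher) and 665 and 241 with upper-quartile factors (0.55 higher). The count was 551 without HS 2 h and 539 without HS 4 h. cysP did not pass without HS 1 h (−5.32) or 2 h (−5.31), hisG without HS 2 h (−3.62), HS 4 h (−3.61) or MOPS 4 h (−2.21), ibpB without HS 2 h (5.09), and pstS without HS 1, 2 or 4 h or MOPS 1 or 4 h (2.28 to 3.90).

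The course of the heat shock was tested as a slope per doubling of time over its 5 libraries. htpG fell by 1.33 ± 0.24 on the log2 scale per doubling (SE, n = 5 libraries, edgeR adjusted p = 0.00333), from 4218 CPM at 15 min to 99.9 CPM at 4 h. groL fell by 1.30 ± 0.29 (0.00791), from 10215 to 228 CPM, and hslU by 1.10 ± 0.22 (0.00476). Of 16 genes of the sigma 32 list 9 fell and 1 rose (11 and 1 when adjusted over the list alone; median −0.79; camera adjusted p = 2.31e-06, but adjusted p = 0.499 with an estimated correlation). Envelope stress genes went the other way: 5 of 11 rose (6 when adjusted over the list alone; median 0.55; camera adjusted p = 0.00127, but adjusted p = 0.499 with an estimated correlation), degP by 1.51 ± 0.39 (0.0183), rseB by 1.32 ± 0.20 (0.00151) and rseA by 1.18 ± 0.25 (0.00599).

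**Figure D2:**
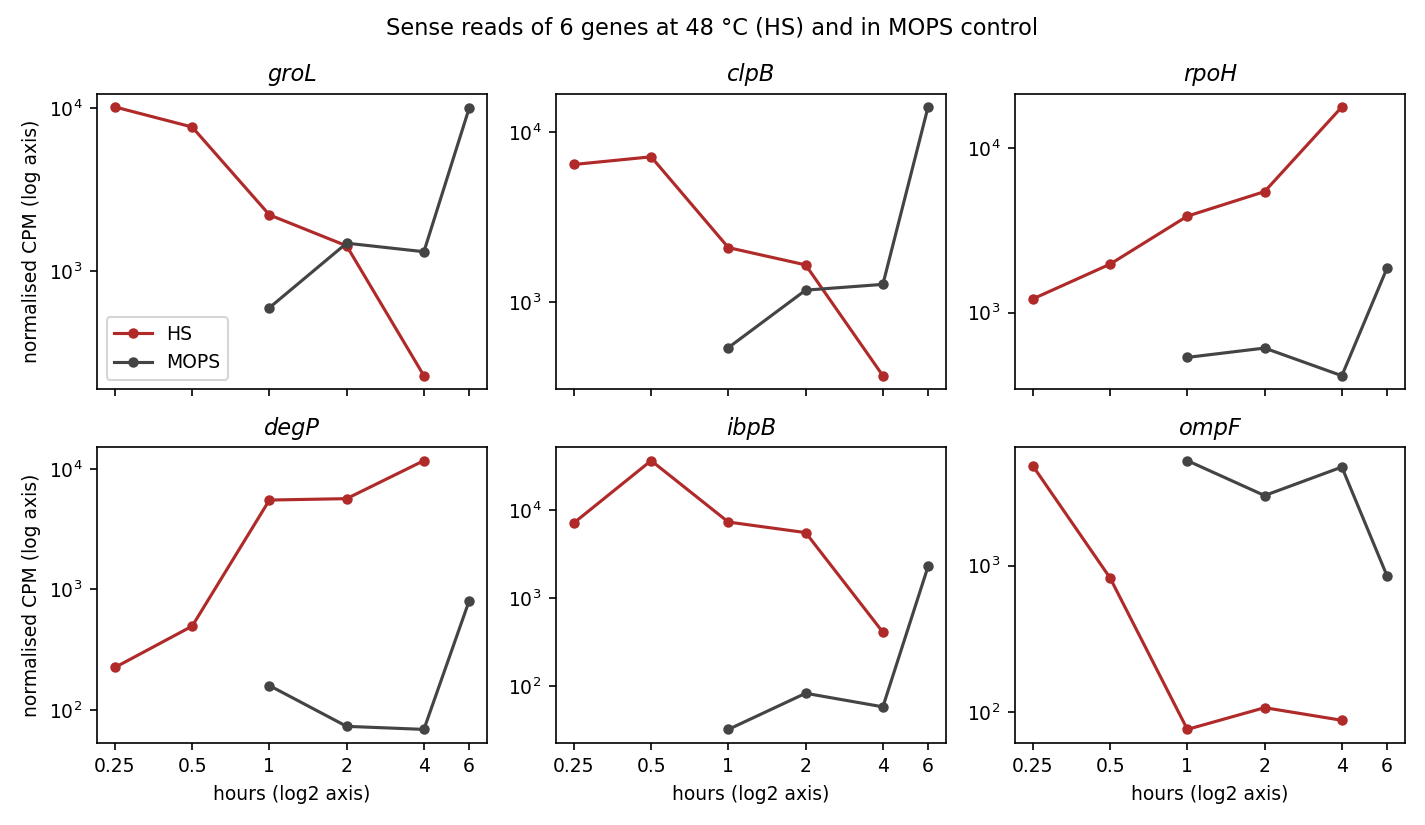
TMM-scaled CPM (log axis) of heat and envelope stress genes in each HS and MOPS library against hours (log axis). groL fell from 10215 to 228 CPM between 15 min and 4 h of HS, while degP went from 226 to 11707 CPM.

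ybfH rose by 2.76 ± 0.25 per doubling (1.90e-05), and the phage shock genes pspD, pspC and pspB by 1.86 ± 0.32 (0.00252), 1.72 ± 0.31 (0.00325) and 1.68 ± 0.27 (0.00169). pyrI fell by 2.06 ± 0.42 (0.00565), carB by 1.87 ± 0.31 (0.00238), cysP by 1.82 ± 0.41 (0.00832) and the flagellar gene fliL by 1.58 ± 0.36 (0.00996). Of 37 flagella and chemotaxis genes 14 fell (28 when adjusted over the list alone; median −0.82; camera adjusted p = 2.31e-06, but adjusted p = 0.625 with an estimated correlation), and of 17 nucleotide synthesis genes 8 fell (12 when adjusted over the list alone; adjusted p = 0.499 with an estimated correlation). In all, 389 of 2150 genes changed, 221 rising and 168 falling (319 and 103 with median-ratio factors, 320 and 95 with upper-quartile factors). The count was 59 without 15 min, 221 without 2 h and 123 without 4 h. Without 15 min carB (−1.20), pyrI (−1.18), cysP (−0.28), fliL (−0.12) and degP (1.23) did not pass, and degP did not pass without 30 min (1.38) or 4 h (1.85). groL (−1.02), hslU (−0.89) and rseA (0.94) did not pass without 4 h.

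The first 30 min of heat have no matched control. HS at 15 and 30 min was set against MOPS at 1 h, which leaves 1 control library assumed to vary like the other groups. htpG was at 4.52 ± 1.69 (SE, edgeR adjusted p = 0.498), groL at 3.91 ± 2.05 (0.579) and clpB at 3.65 ± 1.87 (0.577) on the log2 scale, and 0 genes passed. The median of the 16 sigma 32 genes was 3.27 (camera adjusted p = 5.08e-13, but adjusted p = 0.685 with an estimated correlation), and with 1 control library of another time this p covers the difference from that library alone.

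In MOPS 68 of 2150 genes changed over 1 to 6 h, 59 rising and 9 falling. The arginine breakdown gene astA rose by 4.62 ± 0.81 per doubling (SE, n = 4 libraries, edgeR adjusted p = 0.0139), tnaC by 3.63 ± 0.84 (0.0285), entE of enterobactin synthesis by 3.38 ± 0.80 (0.0315) and csiD by 3.22 ± 0.66 (0.0171). metL fell by 2.49 ± 0.56 (0.0264), yciW by 2.27 ± 0.41 (0.0139), yeeE by 1.94 ± 0.50 (0.0469) and pstA by 1.69 ± 0.44 (0.0477). Of 38 CRP dependent genes 10 rose (16 when adjusted over the list alone; camera adjusted p = 5.68e-08, but adjusted p = 0.281 with an estimated correlation). These slopes rest on 6 h: 0 genes passed without MOPS 6 h, 2 without 2 h and 210 without 4 h, and none of these 8 genes passed without 6 h (astA 0.33, tnaC 1.15, entE −1.17, csiD 0.08, metL −2.44, yciW −2.36, yeeE −1.37, pstA −1.12) or without 2 h (3.99, 3.08, 2.96, 3.01, −2.62, −2.30, −1.88, −1.54). Without 1 h entE (4.56), metL (−0.74), yciW (−1.93), yeeE (−2.65) and pstA (−2.60) did not pass.

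In M-P 20 of 2150 genes changed over time, 4 rising and 16 falling. The sorbitol genes srlB, srlE and srlD fell by 3.68 ± 0.67 (0.0236), 3.40 ± 0.72 (0.0384) and 3.14 ± 0.55 (0.0236) per doubling (SE, edgeR adjusted p), and gatD of galactitol use by 2.63 ± 0.46 (0.0236). The putrescine uptake genes potG, potF and potI rose by 1.94 ± 0.40 (0.0373), 1.63 ± 0.30 (0.0236) and 1.45 ± 0.33 (0.0489). The count was 0 without M-P 1 h, 10 without 4 h and 3 without 6 h, and none of these genes passed without 1 h (srlB −0.76, srlE 0.22, srlD −0.42, gatD −0.48, potG 1.29, potF 1.48, potI 1.13) or 6 h (−3.84, −4.32, −3.80, −3.34, 1.83, 1.10, 1.03). The sugar alcohol genes did not pass without 4 h (srlB −4.96, srlE −3.22, srlD −3.01, gatD −2.53). In M-C 0 of 2150 genes passed with edgeR, 325 had an unadjusted p under 0.05, and DESeq2 called 73; the edgeR count was 12 without M-C 1 h and 10 without 2 h.

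MOPS was compared with exponential LB to describe the move from rich to minimal medium. In MOPS 18 of 37 flagella and chemotaxis genes and 14 of 38 CRP dependent genes were lower. lamB, the maltose porin gene, fell by 7.67 ± 0.77 on the log2 scale (SE; edgeR, 4 libraries against 2, adjusted p = 1.03e-05). Among the genes with the largest falls, tdcE (which may share reads with pflB), tdcF, tdcD and tdcB of threonine breakdown fell by 8.13 ± 1.01 (6.37e-05), 8.08 ± 1.32 (0.000768), 7.74 ± 1.16 (0.000359) and 6.78 ± 1.30 (0.00277). The trehalose genes treC and treB fell by 7.69 ± 1.03 (0.000119) and 7.55 ± 1.04 (0.000161), and srlD by 7.60 ± 1.71 (0.00986). Of 37 flagella and chemotaxis genes 18 fell (23 when adjusted over the list alone; median −4.68; camera adjusted p = 3.06e-29, but adjusted p = 0.179 with an estimated correlation), fliH by 6.04 ± 1.50 (0.0195), fliO by 5.93 ± 1.34 (0.0139) and fliJ by 5.91 ± 1.26 (0.00635). Of 38 CRP dependent genes 14 fell (18 when adjusted over the list alone; median −1.85; camera adjusted p = 1.43e-21, but adjusted p = 0.0619 with an estimated correlation). Of 22 anaerobic and fermentation genes 9 fell (12 when adjusted over the list alone; median −2.33; camera adjusted p = 5.55e-07, but adjusted p = 0.279 with an estimated correlation), the nitrate reductase genes narG by 6.27 ± 1.21 (0.00277) and narH by 5.73 ± 0.94 (0.000768). tnaA, which encodes tryptophanase, fell by 5.56 ± 1.56 (0.0382).

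Of 46 amino acid synthesis genes 5 were higher in MOPS and 41 did not pass, and of 17 nucleotide synthesis genes 2 were higher and 15 did not pass. leuA (ECK120001204), leuC and leuB of leucine synthesis rose by 8.07 ± 2.02 (edgeR adjusted p = 0.0206), 7.17 ± 1.90 (0.0281) and 7.15 ± 1.97 (0.0346). argF rose by 5.78 ± 1.61 (0.0356), yjiG by 5.90 ± 1.35 (0.0111), purE by 4.49 ± 1.13 (0.0208), purC by 4.45 ± 1.09 (0.0183) and dhaL by 3.83 ± 1.02 (0.0291). When adjusted over the list alone 15 amino acid genes (median 2.81; camera adjusted p = 9.71e-12, but adjusted p = 0.423 with an estimated correlation) and 5 nucleotide genes (median 1.99; camera adjusted p = 3.50e-05, but adjusted p = 0.423 with an estimated correlation) rose. glnK, of nitrogen control, had 449 reads in MOPS and 1 in LB, a ratio of 232 (95% counting interval 41.4 to 9187). In all, 132 of 2164 genes changed, 19 higher and 113 lower with edgeR, against 110 higher and 115 lower with DESeq2. The split was 45 and 142 without MOPS 6 h, 1 and 65 without LB at OD600 0.5 and 2 and 81 without LB at OD600 1.0. The count was 66 without LB at OD600 0.5, 83 without LB at OD600 1.0, 87 without MOPS 1 h and 82 without MOPS 2 h. Without LB at OD600 0.5 narG (0.35), narH (−1.02), srlD (−5.25) and yjiG (5.08) did not pass, nor did tdcF (−2.19) and glnK (6.03) without LB at OD600 1.0. Without LB at OD600 0.5 or 1.0, respectively, leuA (7.98, 8.13), leuC (7.24, 7.08), leuB (6.81, 7.56), argF (5.96, 5.54), purC (4.32, 4.52), purE (5.05, 4.04), dhaL (3.44, 4.29) and tnaA (−5.21, −5.97) did not pass. The same held without 1 MOPS library for argF (1 h 5.01, 4 h 5.43), leuB (2 h 6.93, 4 h 6.53), leuC (2 h 7.08), dhaL (4 h 3.09), fliH (1 h −5.94, 2 h −5.80) and tnaA (1, 2 or 4 h, −5.23 to −5.20).

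**Figure D3:**
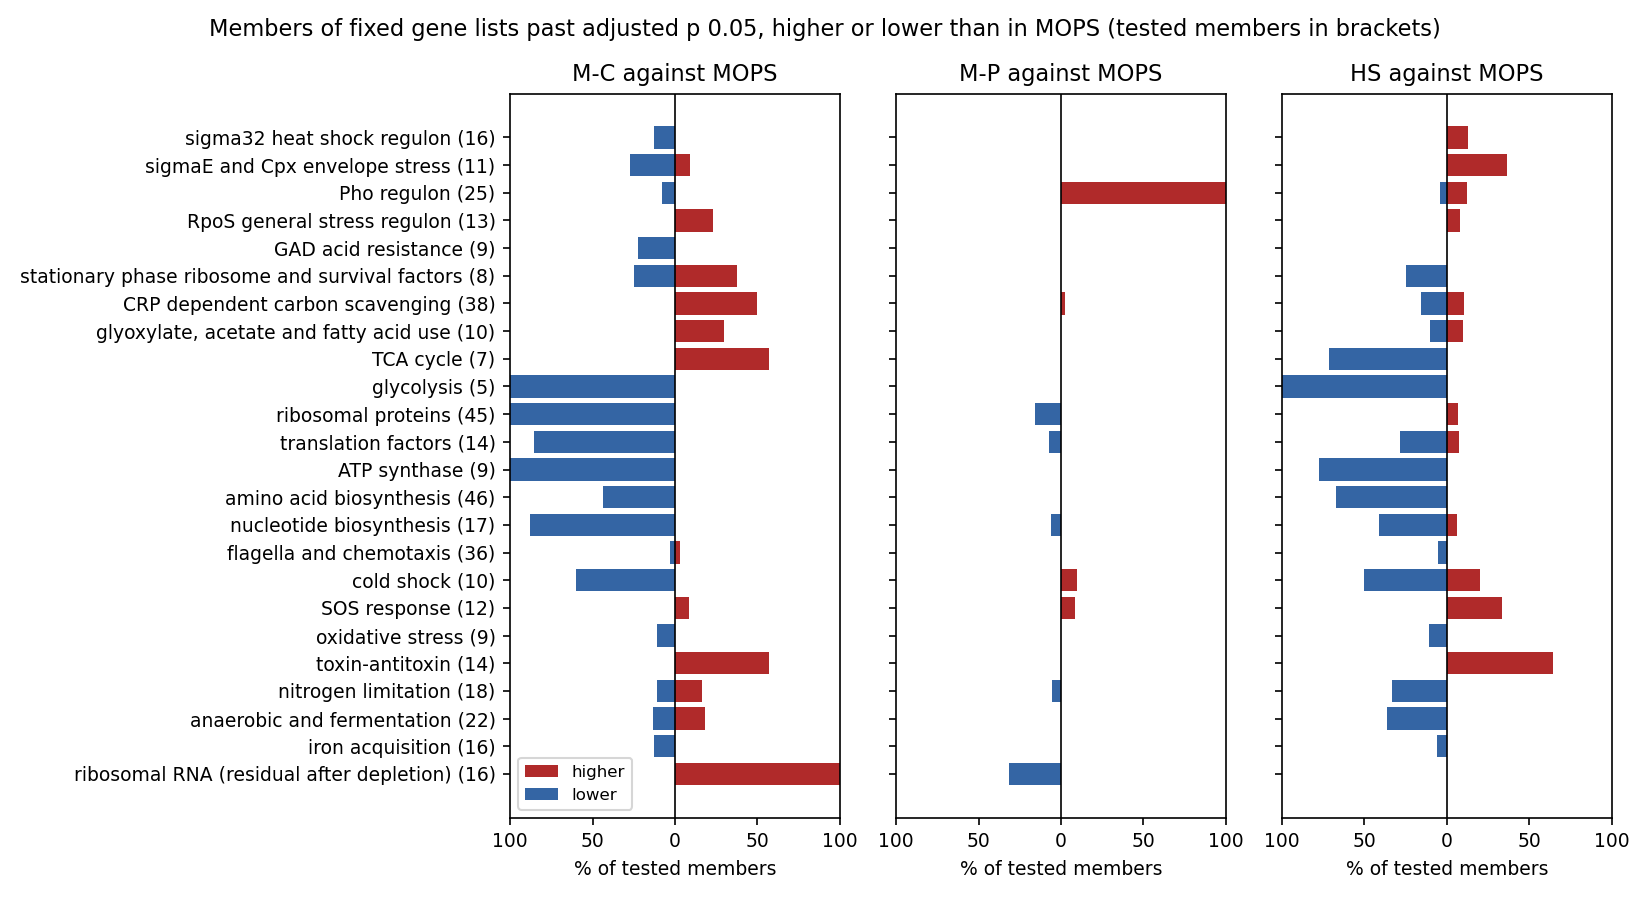
Share of the tested members of each gene list that rose or fell in M-C, M-P and HS against MOPS, in percent. All 45 ribosomal protein genes fell in M-C and all 25 Pho regulon genes rose in M-P.

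LB at OD600 3.0 has 1 library, so its differences from exponential LB have no replicate check and no p-value. Over 1912 genes its Spearman's rho was 0.903 with MOPS 6 h and 0.727 with LB at OD600 1.0, and argF and leuA were also higher, and 18 of 37 flagella and chemotaxis genes lower, in MOPS than in exponential LB. Whether the RNA libraries of LB at OD600 3.0 and MOPS 6 h were exchanged stays open, as described below. Single genes are given here, the largest ratios by the naming rule, and no list was tested. argF was at 6.12 and 6.61 on the log2 scale against OD600 0.5 and 1.0 (2408 reads at OD600 3.0), leuA at 6.08 and 6.01, astA at 6.06 and 6.78, csiD at 7.52 and 5.94, lsrC at 5.61 and 5.48, and fadD at 5.44 and 5.31 (2329 reads). Among the lower, the flagellar gene fliM was at −7.86 and −7.71 (6 reads), fliG at −7.42 and −7.52 (8 reads) and flgE at −7.28 and −6.66 (20 reads). fliI had 1 read at OD600 3.0, or 0.760 CPM with a 95% counting interval of 0.0192 to 4.23 CPM, against 344 and 451 CPM at OD600 0.5 and 1.0, scaled over the LB libraries. Of 1895 genes 174 were over 4-fold higher and 136 over 4-fold lower than in both exponential libraries.

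The share of reads on the antisense strand was compared between the stresses and MOPS. It was 1.24% ± 0.527 in HS (SD, n = 5) and 0.327% ± 0.0648 in MOPS (n = 4), a difference of 0.914 points. The exact two-sided permutation p was 0.0159, the smallest that 5 against 4 can give (adjusted over 3 comparisons 0.0476). This test takes the times of a condition as replicates, and HS at 15 and 30 min has no MOPS library of its time. Without these 2 libraries the difference was 1.18 points (exact permutation p = 0.0571, the smallest that 3 against 4 can give). All 5 HS libraries, at 0.683%, 0.987%, 1.24%, 1.20% and 2.10% from 15 min to 4 h, lay above all 4 MOPS libraries, which reached 0.404%. M-P was at 0.454% ± 0.121 (n = 4; exact permutation p = 0.143, adjusted 0.214) and M-C at 0.219% ± 0.134 (n = 4; exact permutation p = 0.257, adjusted 0.257). With ssrA left out the shares were 2.32% ± 0.679 in HS (n = 5), 0.707% ± 0.284 in MOPS, 1.05% ± 0.262 in M-P and 1.64% ± 0.558 in M-C (n = 4 each), and M-C was then above MOPS (exact permutation p = 0.0286). LB was at 0.475% and 0.482% in exponential growth and at 0.551% at OD600 3.0 (1 library, Wilson 95% interval 0.540% to 0.562%).

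**Figure D4:**
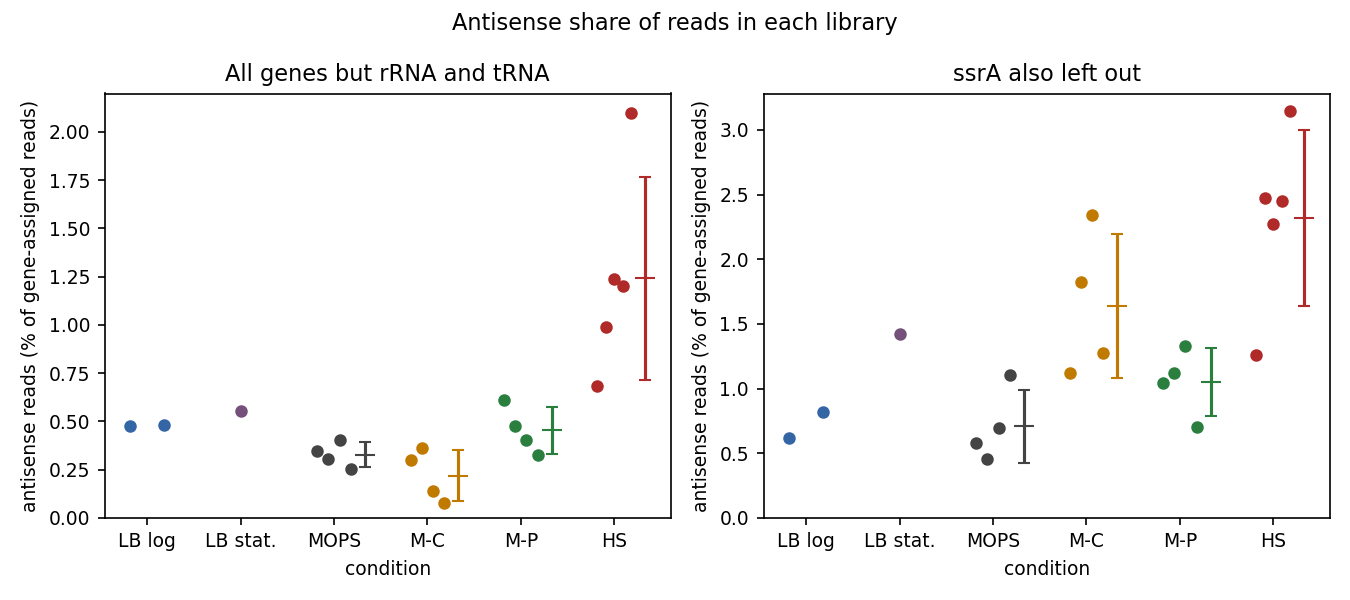
Antisense reads in percent of gene-assigned reads for each library, grouped by condition, with ssrA kept (left) and left out (right). The mean and SD are drawn for MOPS, M-C, M-P and HS only. With ssrA kept, the 5 HS libraries lay between 0.683% and 2.10%, above the 4 MOPS libraries at up to 0.404%.

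Antisense reads were then tested gene by gene. In HS 370 of 799 genes changed, 368 higher and 2 lower. For up to 124 genes of a library the deposited antisense length exceeds that of the gene. Neighbouring genes may therefore share antisense reads, and the counts of genes need not be separate transcripts. gshA, of glutathione synthesis (2812905 to 2814461, minus strand), had antisense reads that rose by 9.12 ± 1.47 (SE, edgeR adjusted p = 4.66e-05). nuoF, pheL and symE had 0 antisense reads in MOPS and were at least 69.8-fold, 165-fold and 154-fold higher in HS; the counts of pheL at HS 1, 2 and 4 h were those of its neighbour raiA, and that of nuoF at 4 h was that of nuoG. yadN had 292 and 1, a ratio of 303 (95% counting interval 53.9 to 12004). ibsA fell by 3.11 ± 1.00 (0.0140), and not past the test without HS 1 h (−2.57) or 4 h (−3.05). Scaled by the antisense counts themselves, which moved the median gene by −1.36, 75 were higher and 17 lower. The count was 235 without HS 2 h, 240 without MOPS 2 h and 242 without MOPS 4 h.

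In M-C antisense reads changed at 51 of 799 genes, 46 higher and 5 lower. yaiE rose by 4.83 ± 0.77 (SE, edgeR adjusted p = 0.000282), hypD by 3.89 ± 0.78 (0.00469), yidZ by 3.48 ± 0.71 (0.00494) and ygfK by 2.43 ± 0.57 (0.0113). ymfM had 506 reads and 1, a ratio of 2268 (95% counting interval 405 to 89742), but at M-C 1 and 2 h its antisense counts were those of its neighbour ymfL (101 and 210 CPM each), which did not pass in M-C (−0.11 ± 1.06, adjusted p = 0.991). proA had 0 in M-C and was at least 18.8-fold lower, glnW had 3 and 210 (ratio 0.0640, 0.0131 to 0.190), and yghE fell by 3.61 ± 1.04 (0.0328). Scaled by the antisense counts, with the median gene moved by −1.17, 6 were higher and 31 lower. The count was 87 without MOPS 6 h, 21 without M-C 2 h and 27 without M-C 4 h; ygfK did not pass without M-C 2 h (2.00), nor did glnW (−9.31 to −3.04) or yghE (−3.94 to −3.31) without any 1 library but MOPS 6 h, proA without any but MOPS 1 or 4 h, or ymfM without MOPS 1, 2 or 4 h or M-C 2 or 4 h (6.85 to 9.86).

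In M-P antisense reads changed at 29 of 799 genes, 26 higher and 3 lower. yjjA rose by 5.53 ± 0.73 (SE, edgeR adjusted p = 0.000104), rbsB by 4.44 ± 0.83 (0.00417), sgcE by 4.15 ± 0.87 (0.00849), csgA by 3.95 ± 0.89 (0.0145) and dps by 3.88 ± 0.79 (0.00666). metU fell by 4.86 ± 0.78 (0.000616), ymfL by 4.54 ± 1.23 (0.0363) and glnW by 2.95 ± 0.81 (0.0494); metU and glnW had the same antisense counts at MOPS 2, 4 and 6 h. Scaled by the antisense counts (median gene −0.49), 10 were higher and 3 lower. The count was 15 without MOPS 2 h, 6 without MOPS 4 h, 51 without MOPS 6 h, 6 without M-P 4 h and 44 without M-P 6 h. dps (3.22) and sgcE (3.71) did not pass without MOPS 4 h, nor rbsB without M-P 4 h (3.72), csgA without MOPS 2 h (4.03), MOPS 4 h (3.03) or M-P 4 h (3.44), ymfL without MOPS 2 or 4 h or M-P 1, 2 or 4 h (−4.62 to −4.28), or glnW without any but M-P 1 h (−3.29 to −2.29).

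The ratio of antisense to sense reads shows where the strands moved apart. In HS it changed at 314 of 928 genes, 293 higher and 21 lower (170 without HS 2 h, 196 without HS 4 h and 182 without MOPS 4 h). In M-C it changed at 170, 119 higher and 51 lower (101 without MOPS 2 h and 72 without M-C 2 h). In M-P it changed at 39, 18 higher and 21 lower, and at 25 (9 and 16) without a strand by time term. The M-P balance turned with the library left out: 67 higher and 23 lower without MOPS 6 h, 52 and 22 without M-P 6 h and 29 and 22 without M-P 1 h, but 8 and 15 without MOPS 2 h, 5 and 16 without MOPS 4 h, 4 and 13 without M-P 2 h and 6 and 15 without M-P 4 h. Across 751 genes, which are not independent replicates, the changes on the 2 strands had r = 0.299 and rho = 0.264 in HS, r = −0.0550 and rho = −0.0324 in M-C, and r = −0.0412 and rho = −0.00660 in M-P. With sense from 1 and 4 h and antisense from the other time, r was 0.180 in HS.

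The responses were compared with each other. M-C and HS shared 65 genes higher and 178 lower (113 and 118 with median-ratio factors), M-P and HS 34 and 1, and M-C and M-P 8 and 20. Genes called in both but in opposite directions numbered 70 for M-C and HS, 18 for M-P and HS and 21 for M-C and M-P. Independent lists of these sizes would share 57.1 higher and 97.8 lower for M-C and HS, 22.4 and 9.03 for M-P and HS, and 12.9 and 13.7 for M-C and M-P. Unchanged groups simulated against the same MOPS libraries shared 0 in each case. With no condition effect few genes can be called at all, so this 0 was nearly fixed in advance. It does not give the overlap expected for lists of these sizes with shared controls. With the MOPS libraries split so that each comparison had its own, M-C and HS shared 22 and 94 or 25 and 106, M-P and HS 6 and 2 or 7 and 0, and M-C and M-P 2 and 7 or 0 and 13. The covariance of the fold changes was 0.887 for M-C and HS (0.221 simulated), 0.489 for M-P and HS (0.221) and 0.337 for M-C and M-P (0.223), and r was 0.194 (0.342), 0.160 (0.469) and 0.104 (0.385). With the MOPS libraries split, r was −0.0381 or 0.0965 for M-C and HS and 0.114 or −0.0485 for M-P and HS. It was −0.184 or 0.129 for M-C and M-P, so in each pair its sign depended on the split.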

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

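The tests of carry-over of DNA, of another preparation or mapping of M-C, of the MOPS 6 h pattern, of the peptide counts and of the regrouped libraries were chosen after the results were seen. The tests of strand leakage, of ssrA and of few reads at M-C 4 h and 6 h were written before.

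Antisense reads took a higher share in HS than in MOPS. Of the possible technical sources, strand leakage, carried-over DNA and the share of ssrA were tested first. The antisense to sense ratio at ssrA was taken as the rate at which sense reads leak. It accounts for at most 0.0115% of the antisense reads outside ssrA in HS from 1 h on. The median ratio at the most abundant protein-coding genes without a listed gene close by on the other strand accounts for 0.903% to 1.22% of them. No prediction was written for that second rate. A uniform rate per kb, as carried-over genomic DNA would give, accounts for at most 18.2% of the antisense reads in HS from 1 h on. With ssrA left out of both strands HS was still 1.61 points above MOPS. These results argue against the 3 sources as the whole source. Another preparation of the HS libraries was not tested, since no kit or platform is assigned to a library. It cannot be told apart from a response of antisense transcription to heat. Such a response may be behind the rise, as a hypothesis found and tested on the same data.

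Ribosomal protein genes were lower in M-C than in MOPS, in libraries where ssrA took most reads. With ssrA left out before scaling the list's median was still −2.94, and without M-C 4 h and 6 h 42 of 45 genes were still called lower, which argues against both as the whole source. The lowest rRNA share of reads outside ssrA in M-C was 4.87%, and the highest elsewhere was 2.14%. Another preparation or mapping of the M-C libraries and a response to the loss of carbon cannot be told apart, since the condition and any such difference coincide.

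MOPS at 6 h was closer to LB at OD600 3.0 than to MOPS at 4 h. Over 1912 genes, Spearman's rho of MOPS 6 h was 0.903 with LB at OD600 3.0 and 0.740 with MOPS 4 h, and LB at OD600 3.0 had 0.808 with MOPS 4 h, a difference of −0.0682 of the kind an exchange of the RNA libraries would give. Peptide counts argue against an exchange of whole samples: over 661 genes MOPS 6 h had 0.923 with MOPS 4 h and LB at OD600 3.0 had 0.790, a difference of 0.133. Of 27 carbon scavenging genes that rose in M-C in a fit without MOPS 6 h, 24 were higher at MOPS 6 h than at 4 h, with a median log2 ratio of 2.24, above all 10000 random lists, as a carbon source running out would give. MOPS 4 h served both in choosing these genes and as the reference, which favours a rise. The random lists were not chosen that way, so they do not allow for it. Both an exchange of RNA libraries and carbon running out could be the source and stay open.

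Some libraries lay far from the others of their group, in 12 of 72 groups of values tested. Independent normal replicates would give about 1 in 20. The values here are unlogged and come from different times, and several of the 12 are of MOPS 6 h. The 12 therefore cannot be read against that rate. In MOPS the 6 h library held ugpB at 233 CPM (others 6.03 to 10.1), cstA at 6187 (89.3 to 201), groL at 10012 (596 to 1485), clpB at 13997 (543 to 1275), rpoH at 1865 (415 to 611) and tnaA at 1170 (6.81 to 30.9), and rRNA at 2.14% of reads outside ssrA (0.388% to 0.514%). MOPS at 2 h held rpsA at 6604 CPM (1932 to 2637). HS at 4 h held rpoH at 17713 CPM (1213 to 5431) and rRNA at 1.22% (0.526% to 0.711%). M-P held lamB at 26.2 CPM at 1 h (6.22 to 8.89) and tnaA at 67.2 CPM at 6 h (10.8 to 16.2).

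Responses differed between the stresses by a test of the difference itself. M-C and M-P differed at 933 genes (306 higher in M-C, 627 lower), HS and M-P at 945 (496 and 449) and HS and M-C at 965 (611 and 354). Between HS and M-C 43 of 45 ribosomal protein genes were higher in HS (median 3.48) and 21 of 38 carbon scavenging genes lower (median −2.44). Slopes over time differed from those of MOPS at 38 genes in HS, 20 in M-C and 46 in M-P. The MOPS slopes rest on MOPS 6 h, and these differences were not fitted without it.

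Peptide counts, a column outside the comparisons above, carried signals of their own. The 7 Pho regulon proteins with values took 3.60% ± 2.49 of peptides in M-P and 0.263% ± 0.0248 in MOPS (SD, n = 4 each). The exact permutation p was 0.0286, the smallest that 4 against 4 can give. In M-P the share went from 1.04% at 1 h through 2.19% and 4.54% to 6.62% at 6 h. Its SD is thus a rise over time, and the test takes these times as replicates. The 12 sigma 32 proteins took 7.49% ± 0.992 in HS (n = 5) and 4.53% ± 0.220 in MOPS (n = 4, exact permutation p = 0.0159), with GroL at 813 ± 209 counts against 416 ± 47.0. Ribosomal proteins took 14.7% ± 1.88 in HS (n = 5) against 12.1% ± 0.148 in MOPS (n = 4, exact permutation p = 0.0159). The 26 carbon scavenging proteins took 8.19% ± 0.175 in M-C against 6.56% ± 0.694 (n = 4 each, exact permutation p = 0.0286). Each p adjusted over 6 such tests was 0.0343.

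Other splits of the same libraries were fitted for the counts of genes. The libraries are matched by time, and of the 32 splits for M-C and for M-P only 8 part the libraries of each time, which is too few for a share under 0.05. The real counts and the highest of the other splits were 828 and 387 genes in M-C and 156 and 61 in M-P, 51 and 13 for antisense in M-C and 29 and 20 in M-P, and 170 and 129 for the ratio in M-C and 39 and 22 in M-P. Each real count was reached by 1 split, the real one. For HS the 10 splits are too few as well, with 831 genes against 0, 370 against 0 for antisense, and 314 against 0 for the ratio.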

How the results depend on the processing

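The alternatives that leave out ssrA, M-C 4 h and 6 h together (also with MOPS 6 h), or repeated antisense counts were chosen after the data were seen. Of 257 values under an alternative that answer a comparison, 168 kept their call or stayed within 1.5 times the count, 84 moved, 2 were reversed, 2 became stronger and 1 weaker; of 6386 values of single genes 5569 kept their direction and call, 746 became weaker (465 of them with 1 library left out), 59 stronger and 12 were reversed. In 2 of the 168 the larger side changed: antisense in M-C scaled by antisense counts (6 higher, 31 lower, 11 of the 51 genes shared) and the ratio in M-P without 1 h (29 and 22). Where no cause is named, the cause was not tested. With DESeq2 the counts of genes were 283 in M-P, 225 in MOPS against LB (110 higher, 115 lower), 586, 224, 73 and 70 for the slopes of HS, MOPS, M-C and M-P, and 112 and 60 for antisense in M-C and M-P. With the 2 conditions alone they were 48 in M-P, 53 in MOPS against LB, 774 in M-C and 1126 in HS (618 higher, 508 lower), and 63 with LB at OD600 1.0 alone. With a mean of 50 reads, which leaves fewer genes, they were 492 in HS and 195 and 41 for the slopes of HS and MOPS. With hours in place of log2 hours the slopes numbered 153, 169, 11 and 0 in HS, MOPS, M-C and M-P. On log2 hours 124 of the slopes in HS were 2-fold or more. HS at 15 and 30 min against MOPS 1 h gave 0 genes.

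Scaled by the antisense counts, antisense genes numbered 13 in M-P and 92 in HS; with a mean of 10 antisense reads 174 in HS, and without M-C 4 h and 6 h 32 in M-C. The ratio gave 87, 17 and 112 genes in M-C, M-P and HS with a mean of 10 antisense reads, and 25 in M-P without the strand by time term. With that filter the correlation of the strands was −0.172 in M-C and 0.0447 in M-P, and 0.180 in HS with separate libraries for each strand. LB at OD600 3.0 had 684 genes past 2-fold and 153 past 8-fold. At an adjusted p under 0.01 the overlaps were 6 (M-C and M-P), 89 (M-C and HS) and 9 (M-P and HS). With an estimated correlation 0, 1 and 0 gene lists passed in M-C, M-P and HS, of 11, 8 and 9. The antisense share of M-C turned to 0.0465 points above MOPS with genes of 10 or more sense reads in each library (exact permutation p = 0.429) and 0.934 points above with ssrA left out (p = 0.0286), that of M-P passed at 0.0306 with the same genes and at 0.479 as a median over genes (exact p = 0.0286 for both), and that of HS without 15 and 30 min was 1.18 points above at the smallest p its 3 libraries allow (exact p = 0.0571).

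Single genes that turned: in HS at 15 and 30 min deoD (0.31), rpmA (−0.28) and pyrI (1.35), pyrI with all 5 HS libraries (1.11), and narG with LB at OD600 1.0 alone (0.38). With 1 library left out, narG ranged from −7.28 to 0.35 (without LB at OD600 0.5), the HS slopes of cysC from −2.09 to 0.10, cysN from −2.37 to 0.26 and flgK from −1.97 to 0.051 (all 3 without 15 min), the M-P slope of srlE from −4.32 to 0.22 (without 1 h), and the MOPS slopes of entE from −1.17 (without 6 h) to 4.56 and astE from −0.19 (without 6 h) to 5.01. With each library left out in turn the counts ranged over 570 to 980 in M-C, 79 to 259 in M-P, 539 to 984 in HS and 66 to 187 in MOPS against LB; for slopes 59 to 335 in HS, 0 to 210 in MOPS, 0 to 12 in M-C and 0 to 23 in M-P; for antisense 21 to 87 in M-C, 6 to 51 in M-P and 235 to 418 in HS; for the ratio 72 to 221, 17 to 90 and 170 to 378; and for the antisense share −0.155 to −0.0611 points in M-C, 0.0747 to 0.169 in M-P and 0.700 to 1.05 in HS. The planned changes of pseudocount and the sums of paired tables were not run, since the tables hold counts and the pairs were identical.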

Other observations

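The gene lists of this part were fixed in advance, and the tests of peptide counts were chosen after the data were seen. Responses to cold, DNA damage and survival moved in part and were tested like the other lists. Of 10 cold shock genes 6 fell in M-C (median −1.39; camera adjusted p = 0.165), deaD, an RNA helicase gene, by 3.95 ± 0.89 on the log2 scale (SE, edgeR adjusted p = 0.00321), while 2 rose and 5 fell in HS (camera adjusted p = 0.180) and 1 rose in M-P (0.715). Of 12 SOS response genes 4 rose in HS, lexA by 2.11 ± 0.63 (edgeR adjusted p = 0.0169; 1.37 and not past the test without HS 4 h), 1 in M-C (camera adjusted p = 0.205; 3 without MOPS 6 h, and 5 with 0.00883 without M-C 4 h and 6 h) and 1 in M-P (0.661). Of 8 stationary phase factor genes 3 rose and 2 fell in M-C (camera adjusted p = 0.107, and 0.0394 without MOPS 6 h), and 2 fell in HS (0.265; 4 without MOPS 6 h) and 0 changed in M-P (0.965). Of 9 genes of GAD acid resistance 2 fell in M-C (camera adjusted p = 0.728), and 0 changed in HS (0.993) or past the test in M-P, where the list's median was 1.40 and 2 rose when adjusted over the list alone (camera adjusted p = 0.0379, but adjusted p = 0.809 with an estimated correlation, 0.157 without MOPS 6 h, 0.0919 with no time block and 0.0524 with upper-quartile factors).

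Of 18 nitrogen limitation genes 3 rose and 2 fell in M-C (camera adjusted p = 0.129; 6 rose without MOPS 6 h, with 0.0255, and 0 rose and 3 fell with no time block) and 1 fell in M-P (0.0562, and 0.0431 to 0.0478 under 3 other scalings, but 0.886 without MOPS 6 h). Of 22 anaerobic genes 4 rose and 3 fell in M-C (camera adjusted p = 0.624), frdD of fumarate reductase rising by 2.82 ± 0.52 (edgeR adjusted p = 0.000953). Of 16 iron uptake genes 2 fell in M-C and 1 in HS, of 9 oxidative stress genes 1 fell in each, and of 36 flagella and chemotaxis genes 1 rose and 1 fell in M-C and 2 fell in HS (camera adjusted p = 0.0513). Without MOPS 6 h, 4 oxidative stress genes rose in M-C (camera adjusted p = 0.0177), 4 iron uptake genes rose in HS (0.326), and 5 flagellar genes fell in M-C (0.883) and 8 in HS (0.02004). Of 25 Pho regulon genes 2 fell in M-C (4 fell and 3 rose without MOPS 6 h) and 3 rose and 1 fell in HS (camera adjusted p = 0.628 and 0.808), pstC by 4.04 ± 1.05 in M-C (edgeR adjusted p = 0.00777), while phoR, the sensor gene, rose by 3.45 ± 0.63 in HS (0.000838). In M-P 0 of 46 amino acid synthesis genes changed (camera adjusted p = 0.144), 1 of 38 carbon scavenging genes rose (0.298), and the medians of the sigma 32, ATP synthase and translation factor lists were −0.74, −0.94 and −0.53 (camera adjusted p = 0.0322, 0.0243 and 0.0317, but adjusted p = 0.895, 0.809 and 0.809 with an estimated correlation). Without MOPS 6 h these medians were −0.23, −1.48 and −0.88 (camera adjusted p = 0.612, 3.02e-05 and 0.000309).

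In HS 4 of 14 translation factor genes fell and 1 rose, with a median of −0.39 that turns to 0.08 with median-ratio and 0.18 with upper-quartile factors (camera adjusted p = 0.368). Of 38 carbon scavenging genes 4 rose and 6 fell in HS (camera adjusted p = 0.536; 10 rose without MOPS 6 h), of 10 for glyoxylate, acetate and fatty acid use 1 rose and 1 fell (0.743; 3 rose without MOPS 6 h), of 13 RpoS genes 1 rose (0.269) and of 16 rRNA genes 0 changed (0.180). In M-P 0 genes of the RpoS, TCA cycle, glycolysis, toxin-antitoxin and oxidative stress lists changed (camera adjusted p = 0.965, 0.944, 0.965, 0.298 and 0.965). That rests on MOPS 6 h for part of them: without it the RpoS list had a median of 1.10 (camera adjusted p = 0.0310) and the oxidative stress list one of 1.03 (0.00934), with 0 single genes past the test, and the anaerobic list passed as lower (median −0.42, 0.0294).

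Peptide counts of single proteins went with their transcripts for the Pho regulon. PhoA was at 161 ± 150 counts in M-P and 1.75 ± 0.500 in MOPS, PstS at 143 ± 68.4 and 18.3 ± 2.99, and UgpB at 76.5 ± 52.5 and 1.50 ± 1.29 (SD, n = 4 each). Ribosomal proteins took 9.33% ± 1.83 of peptides in M-P against 12.1% ± 0.177 in MOPS (SD, n = 4 each, exact permutation p = 0.0286). In M-P their share went from 11.2% at 1 h through 10.4% and 8.45% to 7.21% at 6 h, so its SD is a fall over time. They took 11.4% (10.7% to 12.2%) in M-C against 12.2% ± 0.147 in MOPS (SD, n = 4 each, exact permutation p = 0.0857).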
